A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

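Signals were read per probe from the deposited Feature Extraction files of 8 arrays of the Agilent 4x44K format, and the deposited series matrix was used to check them. The submitters' processing notes name Agilent Feature Extraction without a version, and per the file headers it was version 9.5.1.1. Per the file headers, the processed signals are intensities in arbitrary units after background subtraction, spatial and multiplicative detrending and linear dye normalization by the authors. Per the labels, the red channel (Cy5) holds the immunoprecipitate and the green channel (Cy3) the whole-cell extract used as input. The authors' series matrix holds log10 ratios of red to green that were not centred. Its medians were 0.0425 and 0.0457 in wt (H3K9me2, then Swi6), 0.0217 and 0.0032 in swi7H4, 0.0191 and 0.0113 in dts2, and 0.0319 and 0.0437 in cut4. It differed from the ratios in the deposited array files by no more than 5e-05, the size of its rounding, and on 1 to 14 probes per array those ratios differed from the ratio of the processed signals.

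The value used here was the log2 ratio of the deposited processed signals, centred on the median of each array, an own unit that is not in the files. The medians before centring were 0.14 and 0.15 in wt, 0.07 and 0.01 in swi7H4, 0.06 and 0.04 in dts2, and 0.11 and 0.15 in cut4. Each array held 2513 control spots, which were left out, as were 4 to 20 outlier spots per array. Saturated spots were kept: 41 to 127 per array in the immunoprecipitate channel, 0 to 46 in the input channel and 177 probes on any array.

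Probe coordinates came from the deposited files, and the genome build behind them is not given in the sources used here. They were compared with the reference assembly ASM294v3 through the correlation of the input signal with GC content in 100-kb windows. Chromosomes II and III and chromosome I up to 3773172 matched at offset 0 (r of 0.659 on chromosome I, 0.667 on each of the others), and r there exceeded that at far offsets in 38 of 38 windows of this part of chromosome I, 45 of 45 of chromosome II and 24 of 24 of chromosome III. On the rest of chromosome I (3784546 to 5566771, 6047 probes) r was 0.039 at offset 0 and 0.658 at 6160 bp, so no gene was named there and the coordinates of the array files were used. The matched part held 36594 probes (85.7%), of which 45 match the reference more than once and 135 were not found in it.

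Probes were averaged over 2-kb bins with at least 3 probes (6067 bins, median 7 probes) and over protein-coding genes with at least 2 probes (4161 of 4366 genes with matched coordinates, of 5113 annotated; median 6 probes). Regions were the gene-free stretches around the centromeres (76 probes), the outermost 50 kb of chromosomes I and II (251 probes) and the mating-type region with 5 kb on each side (77 probes). Few probes lie at the centromeres: centromere 1 had 8, centromere 2 had 38 and centromere 3 had 30. Of these 76 probes 1 matches the reference more than once, so multicopy repeats are hardly measured. Central probes lie at least 15 kb inside the gene-free stretch. A bin counted as enriched at a mean log2 ratio of at least 1. With 1 array per group no p-value was computed across probes. Instead the mean of a region was placed among 10000 stretches of as many consecutive probes drawn outside the regions, as a description of these arrays.

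Contrasts across bins or genes were fitted with limma 3.58.1 in R 4.3.3, with an adjusted p (Benjamini-Hochberg) below 0.05. The antibody contrast had strain as block (3 residual degrees of freedom). The strain contrast had the antibody as a term, so it asks what both antibodies of a mutant share, and all mutants are compared with the same pair of wt arrays. A low wt value would therefore show in all 3. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Simulated arrays had the real layout and residual spread. Differences of 1 log2 unit were recovered there at 96% to 99% of bins and 97% to 100% of genes. There were 7 to 16 false calls over bins and 1 to 12 over genes. Smaller differences were not simulated. The noise was drawn independently per array, so these figures do not cover an error shared by the arrays of a strain, such as that of their input. Of 200 raised stretches 200 lay outside the central 95% of random stretches, as did 12 of 200 unchanged ones. These stretches of 30 probes came from independent noise, so they check the procedure and do not give its power on the real arrays.

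Before the data were examined, the contrasts, thresholds, regions, gene lists, most alternatives and the rule for naming genes were fixed. The rule names, per mutant and antibody, the 5 largest increases and 5 largest decreases among genes with at least 3 probes that all differ in 1 direction, if the difference is at least 1. It also names the 5 most positive and 5 most negative genes past the threshold per contrast, the 10 highest genes per antibody in wt, and 2 to 4 members per list as examples. The lists held the mutated loci, subtelomeric genes (7 of 60 measured), heterochromatin-island and Mmi1-regulated meiotic genes (16 of 19), mating-type genes (0 of 4), Tf2 retrotransposons (0 of 13), heterochromatin factors (23 of 26), DNA replication genes (28 of 31), genes of the anaphase-promoting complex (11 of 15), ribosomal protein genes (95 of 141), core histone genes (6 of 11), transfer RNA genes inside and outside the centromeres, and auxotrophic markers (8 of 9), the last read in the input channel. List medians were placed among 10000 draws of genes of like input signal.

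Alternatives chosen beforehand were normexp background correction with an offset of 50, loess within arrays, the deposited series matrix, centring outside the regions, scaling of the arrays to a common spread, only probes above background in every input, the median over probes, outlier spots kept, bins of 1 and 5 kb, thresholds of 0.58 and 1.5, subtelomeres of 20 and 100 kb, pericentromeres changed by 5 kb, probes of several matches left out, no block or the slide as block, leaving out each strain, no minimum number of probes, and trend and robust eBayes. Added after the data were seen were a common input (the mean log2 input of all 8 arrays), removal of the GC trend per array, saturated probes left out, the cut4 labels exchanged, central and outer probes apart (also with the GC trend removed), fits within each slide and a 60-kb window around centromere 1. The mitochondrial genome (66 probes, 53 saturated on some array) was kept out of the regions and used only as a value. The array images were not used here. The result of the anaphase-promoting complex list in dts2 is not reported here.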

Results

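Chromatin immunoprecipitation was read on tiling arrays to map histone H3 dimethylated at lysine 9 (H3K9me2), the mark of fission yeast heterochromatin, and Swi6, the HP1 homologue that binds it. Chromatin came from 4 strains: wild type (wt) and the mutants swi7H4, dts2 and cut4. The swi7 gene is pol1, which encodes the catalytic subunit of DNA polymerase alpha, and cut4 encodes a subunit of the anaphase-promoting complex. The reference annotation used here holds no gene named dts2. Each strain was hybridised once per antibody, so the 8 arrays give 1 array per strain and antibody and no replicates within these groups. Each array carried 45220 spots, of which 42707 were genomic probes with a median spacing of 265 bp. The number of arrays limits the precision.

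Signals lay far above background. The median net input signal per array ranged from 5400 to 8313 intensity units and the median net immunoprecipitate signal from 16860 to 21460, while the SD of the negative controls in the input channel ranged from 4.06 to 8.53. At most 16 probes per array were not above background in the input channel. The log2 ratio of immunoprecipitate to input, centred on the array median, had an SD over probes of 0.55 with H3K9me2 and 0.52 with Swi6 in wt, 0.33 and 0.27 in swi7H4, 0.32 and 0.27 in dts2, and 0.44 and 0.49 in cut4. Wild type and swi7H4 shared 1 slide, and dts2 and cut4 shared the other. H3K9me2 occupied positions 1 and 3 and Swi6 positions 2 and 4 on both slides, so the antibody cannot be separated from the position. The labels do not say whether arrays come from separate cultures, so every p-value here measures only the spread between these arrays. Across probes, the inputs of the arrays of a strain correlated at 0.988 to 0.994, against 0.875 to 0.981 between strains. An error in the input of a strain would thus be shared by its arrays and escape the p-values of the strain contrast.

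The loci named by the strains showed no change that passed a test. At pol1 (SPAC3H5.06C, chromosome I 3430955 to 3436241, 15 probes) the log2 ratio of swi7H4 minus wt over both antibodies was -0.07 (SE 0.0671, limma adjusted p 0.569). At cut4 (SPBC106.09, chromosome II 390910 to 396037, 17 probes) the ratio of the cut4 strain minus wt was 0.01 (adjusted p 0.985). Neither gene passed when adjusted over the list alone. A point mutation would leave no trace in such values, so they do not identify the strains.

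The wild-type arrays ask where Swi6 and H3K9me2 sit in unperturbed cells. In wt, Swi6 was highest at the ends of chromosome I and at the outer centromere probes. The left subtelomere of chromosome I (162 to 49732, 47 probes) had a mean log2 ratio of 1.24 (SD 0.83 over probes), the right subtelomere (5516782 to 5566771 in the coordinates of the array files, 121 probes) 0.77 (SD 0.73), and the outer centromere probes 0.56 (SD 0.73, 41 probes). The centromere probes together stood at 0.25 (SD 0.66, 76 probes), the mating-type region at 0.07 (SD 0.70, 77 probes) and the central domains at -0.10 (SD 0.31, 35 probes). On chromosome II the probes begin at 29534 and end at 4491993, so its outermost parts were not measured. Its end probes stood at -0.11 (left, 75 probes) and -0.20 (right, 8 probes), and they count in the means over all subtelomeres. The ends of chromosome III, next to the ribosomal DNA repeats, stood at -0.13 on the left and -0.05 on the right. With H3K9me2 the same strain gave 0.05 (SD 0.44) at the left subtelomere of chromosome I, -0.08 (SD 0.45) at the right one, 0.19 (SD 0.40) at the outer centromere probes and -0.16 (SD 0.65) at the mating-type region. Among 10000 random stretches of as many probes, taken as a description of these arrays, the wt Swi6 means of pericentromere and subtelomere lay at percentiles 99.96 and 100, and those of H3K9me2 at 83.7 and 71.9. The mating-type means lay at 94.4 with Swi6 and 28.2 with H3K9me2. The wt H3K9me2 means of pericentromere, subtelomere and mating-type region thus did not stand out from random stretches. Whether that precipitation worked poorly was not tested, and this bears on each H3K9me2 change from wt.

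Enriched 2-kb bins, with a mean log2 ratio of at least 1, followed the same regions. Of 6067 bins, 17 were enriched for Swi6 in wt: 8 of 19 in the right and 5 of 7 in the left subtelomere of chromosome I, 2 of 12 in the mating-type region, and 1 each at centromeres 2 and 3. No bin of the wt H3K9me2 array reached 1. The enriched Swi6 bins of swi7H4 numbered 26 and included all 17 of wt, where 0.0729 would be shared by independent draws. In dts2 there were 11, of which 7 were among those of wt. In cut4 the order was the other way round, with 15 bins enriched for H3K9me2, 14 of them among the Swi6 bins of wt, and 3 for Swi6, none of them among the Swi6 bins of wt. Chosen after their values were seen, the 3 Swi6 bins of cut4 began at 3866000 (1.44) and 3982000 (1.03) on chromosome I and at 1686000 (1.34) on chromosome III, and the bin at 3866000 was also enriched with H3K9me2 in cut4 (1.18). The single H3K9me2 bin of swi7H4 began at 4002000 on chromosome I (1.01). The dts2 H3K9me2 array had 0 enriched bins.

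**Figure D1:**
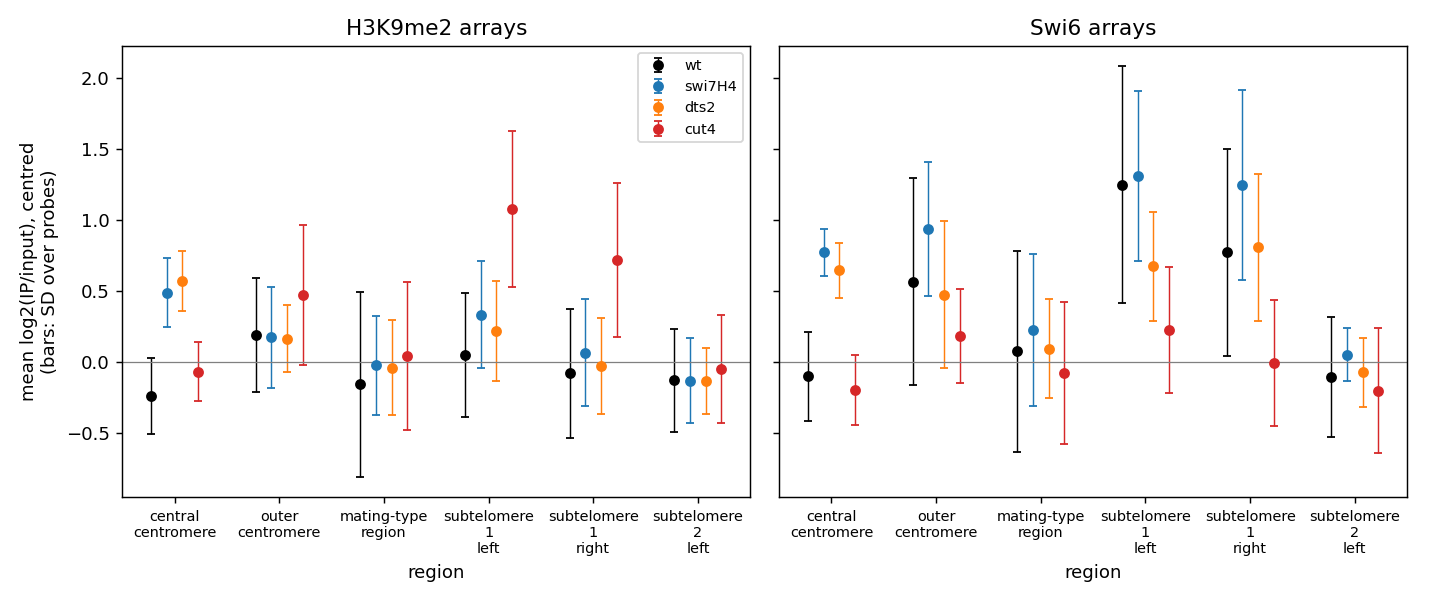
Mean log2 ratio of immunoprecipitate to input per region and array, 1 panel per antibody, with bars for the SD over probes. With Swi6 the left subtelomere of chromosome I stood at 1.24 in wt, 1.31 in swi7H4, 0.67 in dts2 and 0.22 in cut4, and with H3K9me2 at 0.05, 0.33, 0.22 and 1.08.

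Genes with the highest wt Swi6 values were subtelomeric. SPAC212.08C (chromosome I 12158 to 12994, 2 probes) reached 1.83 and tlh1 (chromosome I 1 to 5662, 16 probes), a member of a multicopy family of RecQ-type helicase genes, reached 1.81. The other 8 of the 10 highest lay between 0.67 and 0.79 and included the ribosome-associated chaperone gene sks2 (chromosome II 1106396 to 1108511, 0.79) and the ribosomal protein genes rpl1801 (0.72) and rpl42 (0.72). The wt H3K9me2 array had no subtelomeric gene among its 10 highest, which ranged from 0.59 to 0.71. Its highest was psu1 (chromosome I 1821401 to 1823430, 0.71), a cell wall protein gene, followed by rpl8 (0.68) and sks2 (0.67).

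Comparing Swi6 with H3K9me2 within strains asks whether the reader protein and the mark occupy the same places. No 2-kb bin and no gene passed an adjusted p of 0.05 in limma with strain as block, while 467 bins and 386 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.618 over bins and 0.520 over genes. The difference at the heterochromatic regions changed sign in 1 strain. Over the 286 probes of the outer centromeres, the ends of chromosome I and the mating-type region, Swi6 minus H3K9me2 was 0.67 in wt, 0.84 in swi7H4 and 0.51 in dts2, but -0.52 in cut4. Without cut4, 27 bins and 0 genes passed (336 genes at an unadjusted p under 0.05). Within the slide of wt and swi7H4, 28 bins and 2 genes passed with 1 residual degree of freedom. The genes were SPAC212.08C (1.30, SE 0.103, 2 probes) and tlh1 (1.28, SE 0.131), chosen after their values were seen. These calls rest mostly on the variance pooled over features rather than on replicates. Within the slide of dts2 and cut4 none passed (208 bins and 218 genes at an unadjusted p under 0.05).

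The comparison of swi7H4 with wt asks whether a mutant of DNA polymerase alpha alters heterochromatin. Swi6 stood higher in swi7H4 at the centromeres (mean change 0.60, SD 0.43, 69 of 76 probes higher) and subtelomeres (0.30, SD 0.43, 191 of 251 probes), and both values lay above all random stretches. Most of the subtelomeric difference lay in the input, which differed by -0.22 against 0.11 in the immunoprecipitate, and it was 0.09 with a common input. H3K9me2 changed by 0.32 at the centromeres (SD 0.43, 53 of 76 probes, percentile 98.9) and by 0.12 at the subtelomeres (SD 0.35, percentile 81.1). The mating-type region gave 0.13 with H3K9me2 (percentile 78.8) and 0.15 with Swi6 (percentile 89.4). The centromeric difference was largest in the central domains, where kinetochores assemble. In the 35 central probes, a division made after the values were seen, every probe was higher in swi7H4 with both antibodies, by 0.73 with H3K9me2 (SD 0.23) and 0.87 with Swi6 (SD 0.32). The mean went from -0.24 to 0.48 with H3K9me2 and from -0.10 to 0.77 with Swi6. In the 41 outer probes H3K9me2 differed by -0.02 (SD 0.21, percentile 19.0) and Swi6 by 0.36 (SD 0.36, percentile 99.7). With arrays scaled to a common spread the outer Swi6 difference was larger than 0.36. The outer Swi6 difference went with GC content: stretches of like GC content differed by a mean of 0.28, and with the GC trend removed it was 0.06 (percentile 60.5). That removal took the Swi6 change from 0.60 to 0.24 over all centromere probes and from 0.87 to 0.44 over the central ones, and left the central H3K9me2 change at 0.72. At the right subtelomere of chromosome I Swi6 differed by 0.48 (SD 0.38, 111 of 121 probes), at the left one by 0.07 (SD 0.42, percentile 56.9). The central difference came from the immunoprecipitate channel more than from the input, as the former differed by 0.49 and 0.80 and the latter by -0.22 and -0.10. With normexp background correction the central changes were 0.03 with H3K9me2 and 0.16 with Swi6, inside the range of random stretches.

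**Figure D2:**
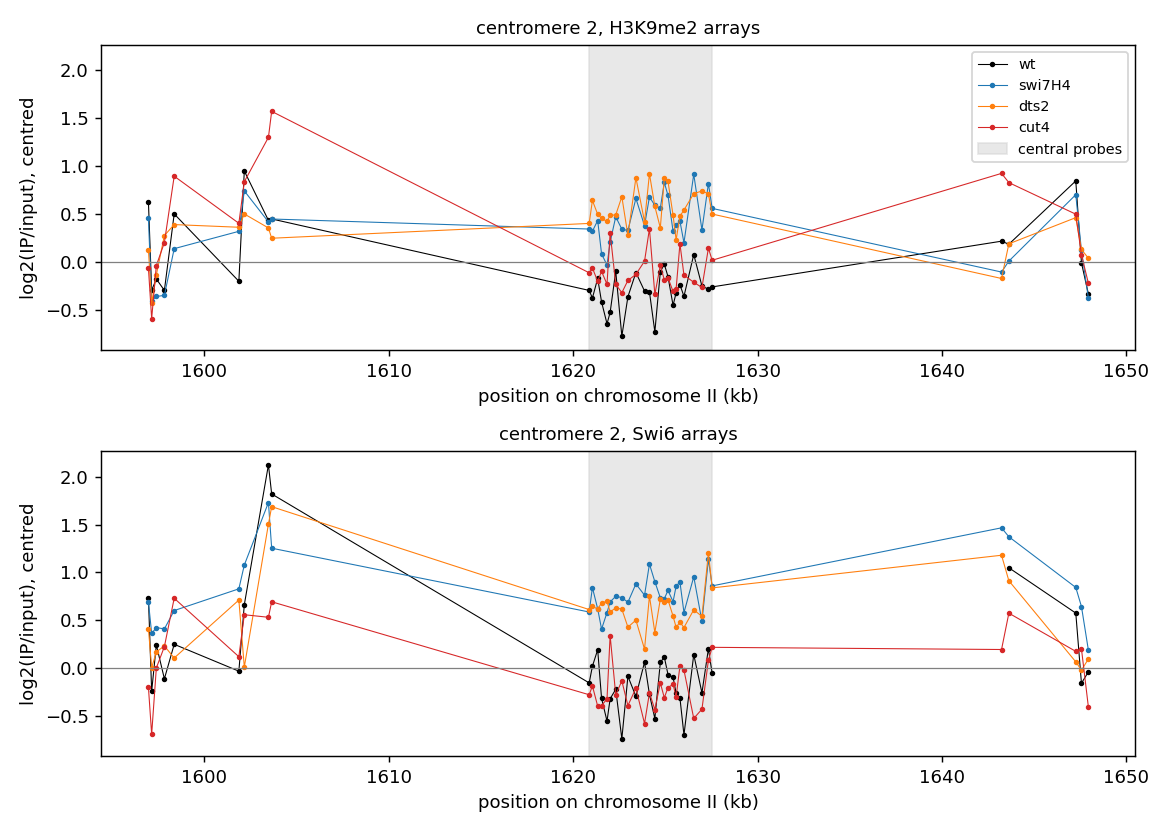
Log2 ratio of each probe against its position at centromere 2 on chromosome II, 1 line per strain and 1 panel per antibody, with the central probes (1620842 to 1627570) shaded. There swi7H4 differed from wt by 0.76 with H3K9me2 and 0.95 with Swi6, and dts2 by 0.88 and 0.79.

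Genes and bins that differed between swi7H4 and wt over both antibodies were many. In limma, with the antibody as a term and both antibodies of a strain as its arrays, 1207 bins passed (939 higher, 268 lower) and 101 genes (89 higher, 12 lower). Most bins lay outside the named regions (917 higher and 266 lower), while 4 of 7 bins passed as higher at centromere 2, 2 of 5 at centromere 3, 4 of 12 in the mating-type region and 10 of 10 on the mitochondrial genome. The uncharacterised SPAC17A2.11 (chromosome I 3577109 to 3578782) was higher by 1.24 (SE 0.119, adjusted p 0.0076), with H3K9me2 at -2.26 in wt and -0.72 in swi7H4. It was followed by SPAC1786.04 (1.21, SE 0.220, adjusted p 0.0364) and, in this order, SPAC56F8.13, SPAC1A6.11 and SPAC23C11.07, the last at 1.07 (SE 0.219). Lower genes were ecl1 (-0.46, SE 0.0807, adjusted p 0.0338), SPCC63.06 (-0.40), the alpha-tubulin gene nda2 (-0.40, adjusted p 0.0448), smp2 (-0.36) and tad3 (-0.35). Under the rule on single arrays, 11 genes qualified with H3K9me2, led by SPAC17A2.11 (1.54), SPAC56F8.13 (1.44), SPAC343.21 (1.35), SPBC16E9.20 (1.31) and SPAC23H4.05C (1.30), and none with Swi6. These calls depended on the input used and on the scaling of the arrays. With arrays scaled to a common spread no bin and no gene passed (903 bins and 496 genes at an unadjusted p under 0.05), SPAC17A2.11 differed by 0.49 (adjusted p 0.452), and over the 1207 called bins the median difference was 0.21 (median SE 0.0826). When all arrays shared a common input, SPAC17A2.11 differed by 0.09 and no gene passed (291 at an unadjusted p under 0.05). There the median difference of the called bins fell from 0.34 (median SE 0.0774) to 0.03 (median SE 0.0695).

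The comparison of dts2 with wt asks the same of a mutant whose gene the labels do not describe. At the central centromere probes dts2 stood above wt by 0.81 with H3K9me2 (SD 0.32, 34 of 35 probes) and 0.75 with Swi6 (SD 0.32, 33 of 35 probes), both outside the central 95% of random stretches. In the outer probes the values were -0.03 (percentile 11.3) and -0.11 (percentile 5.16). With arrays scaled to a common spread the outer Swi6 change had the opposite sign. Over all centromere probes the change was 0.36 with H3K9me2 (SD 0.52, 51 of 76 probes) and 0.29 with Swi6 (SD 0.55, 47 of 76 probes). The latter did not hold with the GC trend removed (-0.00087, percentile 26.1), where Swi6 changed by 0.41 in the central and -0.36 in the outer probes, nor with normexp (-0.03). Swi6 stood lower at the left end of chromosome I in dts2 (0.67 against 1.24, difference -0.57, SD 0.62, 9 of 47 probes higher), below all random stretches, and not at the right end (0.04, percentile 40.3). About as much of the left-end difference lay in the input, which differed by 0.28, as in the immunoprecipitate, which differed by -0.29. Each of the 16 probes of tlh1 was lower (differences of -1.82 to -0.41), and the gene went from 1.81 to 0.75 (difference -1.06, SD 0.40). Of the 47 probes of this left end, 28 match the genome more than once and 21 were saturated on some array. Over all subtelomeres Swi6 differed by -0.07, which became 0.02 without the probes of several matches and 0.03 without the saturated ones. With arrays scaled to a common spread this subtelomere change also had the opposite sign. The Swi6 array had a median absolute deviation of 0.16 in dts2 and 0.30 in wt. Relative to that spread, the mean level at the left end in dts2 was about that of wt. The mating-type region gave 0.12 with H3K9me2 and 0.02 with Swi6 (percentiles 70.3 and 32.8). Since dts2 and wt lay on different slides, strain and slide cannot be told apart for most of these values. At the central probes cut4, on the slide of dts2, changed from wt by only 0.17 with H3K9me2 and -0.10 with Swi6. These values argue against the slide as the whole cause of the central changes in dts2. With normexp the central changes were 0.08 and 0.15, inside the range of random stretches.

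In limma, dts2 differed from wt at 1309 bins (1035 higher, 274 lower) and 192 genes (158 higher, 34 lower). By region, 4 of 7 bins were higher at centromere 2, 1 of 5 at centromere 3, 4 of 12 in the mating-type region and 10 of 10 on the mitochondrial genome. The largest increases were SPAC23C11.07 (1.35, SE 0.219, adjusted p 0.0152), SPAC56F8.13 (1.20), SPAC1786.04 (1.19), SPBC16E9.20 (1.16) and SPAC17A2.11 (1.13). The largest decreases were nda2 (-0.61, SE 0.0803, adjusted p 0.0092), rps1202 (-0.58), rpl1801 (-0.56), rps403 (-0.51) and erg6 (-0.47), an ergosterol synthesis gene. Single arrays named SPBC16E9.20 (1.74, chromosome II 1951792 to 1952828), SPAC56F8.13 (1.54), SPAC17A2.11 (1.30), mug115 (1.21) and SPAC23H4.05C (1.17) with H3K9me2, and tlh1 alone with Swi6. With a common input 0 bins and 0 genes passed in limma (476 bins and 360 genes at an unadjusted p under 0.05), nda2 differed by -0.07, and the median difference over the 1309 called bins went from 0.33 (median SE 0.0770) to -0.00087 (median SE 0.0692). Arrays scaled to a common spread also left 0 bins and 0 genes (1032 and 556 at an unadjusted p under 0.05), with a median difference of 0.22 (median SE 0.0810) over the same bins.

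The comparison of cut4 with wt asks whether a mutant of the anaphase-promoting complex alters heterochromatin. In cut4 the 2 antibodies stood in the opposite order. H3K9me2 stood above wt at the left subtelomere of chromosome I (1.08 against 0.05, difference 1.03, SD 0.53) and at the right one (0.72 against -0.08, difference 0.80, SD 0.47), whereas Swi6 stood below it (0.22 against 1.24, difference -1.02, SD 0.59; and -0.01 against 0.77, difference -0.78, SD 0.58). Over all 251 subtelomeric probes the change was 0.61 with H3K9me2 (211 probes higher) and -0.60 with Swi6 (48 probes higher), the former above and the latter below all random stretches. The H3K9me2 change was made up of 0.30 in the immunoprecipitate and -0.26 in the input, and with a common input the changes were 0.33 and -0.73. At the centromeres it was 0.23 (SD 0.38, percentile 98.0, 56 of 76 probes) and -0.25 (SD 0.57, 23 of 76 probes), in the outer probes 0.28 and -0.38, and in the central ones 0.17 (percentile 88.6) and -0.10 (percentile 5.89). The mating-type region gave 0.20 (SD 0.50, percentile 95.4) and -0.15 (SD 0.60, percentile 0.12). The gene tlh1 went from 0.19 to 1.33 with H3K9me2 and from 1.81 to 0.57 with Swi6. If the antibody labels of the cut4 arrays were exchanged, the subtelomere changes would be 0.04 and -0.03. Which reading holds is not settled by these arrays.

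**Figure D3:**
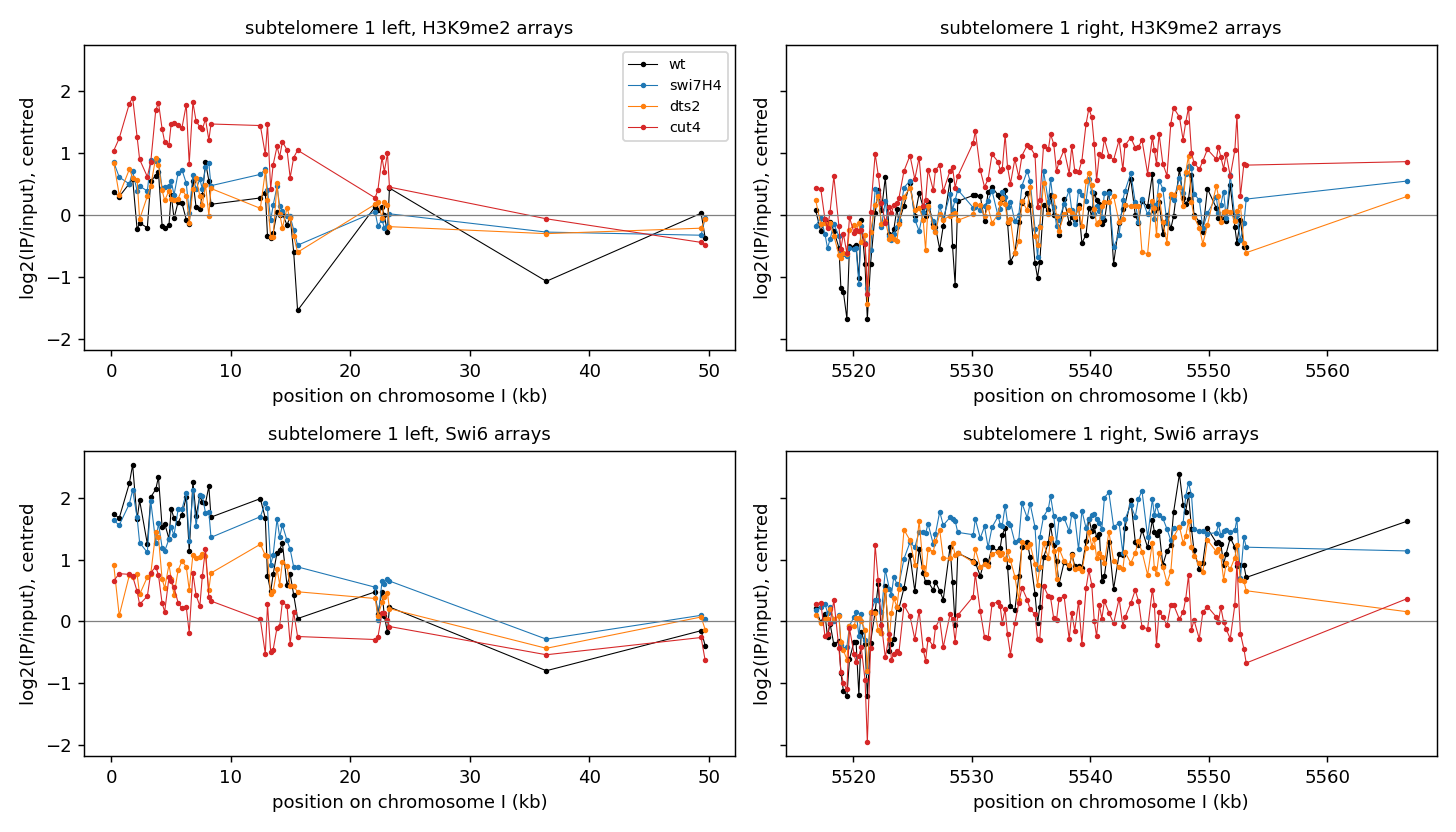
Log2 ratio of each probe against its position at the left and right ends of chromosome I, 1 line per strain, 1 panel per end and antibody. At the left end cut4 had a mean of 1.08 with H3K9me2 and 0.22 with Swi6, and wt 0.05 and 1.24.

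Over both antibodies together, 321 bins (259 higher, 62 lower) and 145 genes (108 higher, 37 lower) differed between cut4 and wt in limma, 320 of the bins outside the named regions and 1 in the mating-type region. The increases were led by fba1 for fructose-bisphosphate aldolase (1.02, SE 0.189, adjusted p 0.0330), eno101 for enolase (0.98, SE 0.214, adjusted p 0.0483), rpl15 (0.88), rps2 (0.83) and SPAC17A2.11 (0.83). Part of these increases followed GC content: with the GC trend removed per array, fba1 stood at 0.44 (adjusted p 0.0124), rpl15 at 0.42 (adjusted p 0.0066) and eno101 at 0.29, where it no longer passed (adjusted p 0.0832). The decreases were led by ema19 (-0.53, SE 0.0919, adjusted p 0.0284), SPBC20F10.03 (-0.48), erg28 (-0.45), snd2 (-0.45) and smp2 (-0.43). Single arrays named SPBC16E9.20 (1.16), tlh1 (1.14), SPAC56F8.13 (1.07), eno101 (1.06) and sap10 (1.01) with H3K9me2, and fba1 (1.03) and tlh1 (-1.24) with Swi6. With a common input 10 bins and 5 genes passed, all in 1 segment of chromosome III (1578000 to 1599999). The 5 genes, coq3, SPCC162.03, SPCC162.02C, SPCC13B11.03C and fmd3, were chosen after their values were seen. Over the 321 called bins the median difference went from 0.37 to 0.13 with a common input, 301 kept their sign and 3 passed both ways. With arrays scaled to a common spread no bin and no gene passed in cut4 (674 and 507 at an unadjusted p under 0.05). That segment, 75 probes over 9 genes that include the alcohol dehydrogenase gene adh1, was higher in cut4 than in the mean of the other strains in every channel: 0.52 (SD 0.35) and 0.50 (SD 0.44) in the input of the H3K9me2 and Swi6 arrays, and 0.59 (SD 0.20) and 0.65 (SD 0.15) in the immunoprecipitate. Its ratio of immunoprecipitate to input was -0.03 and 0.04 in cut4, against -0.27 and -0.19 in wt. In swi7H4 it was -0.01 and -0.11, and in dts2 -0.06 and -0.09. None of the genes named from the strain contrasts passed in limma with a common input (adjusted p 0.409 to 0.970), nor with arrays scaled to a common spread. With the common spread some differences stayed closer to their size (fba1 0.83, eno101 0.80, and nda2 in dts2 -0.54). Others shrank: in swi7H4 SPAC1786.04 went from 1.21 to 0.16 and SPAC23C11.07 from 1.07 to 0.11, and in dts2 SPAC1786.04 went from 1.19 to 0.32. None of the 5 genes of the segment passed with each array's own input.

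**Figure D4:**
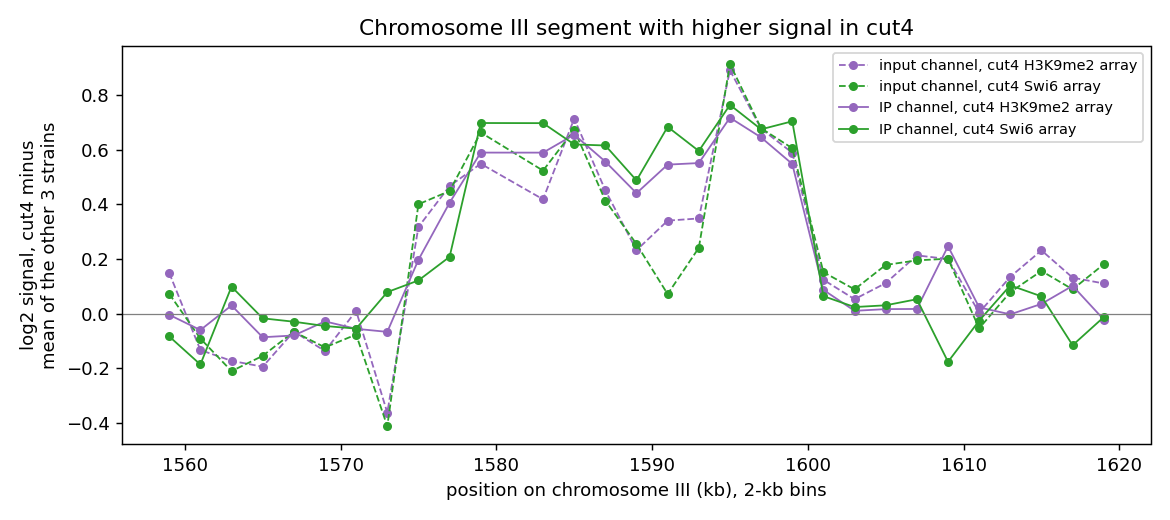
Log2 signal of cut4 minus the mean of the other 3 strains in 2-kb bins along chromosome III, 1 line per channel of each cut4 array. Between 1578000 and 1599999 the means were 0.52 and 0.50 in the input and 0.59 and 0.65 in the immunoprecipitate.

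Gene lists fixed beforehand asked whether the H3K9me2 or Swi6 signal changed over known target genes or over the genes of the machinery. These values are ratios of immunoprecipitate to input over a gene and do not measure its expression. Among 23 heterochromatin factor genes, stc1, whose product links RNA interference to the H3K9 methyltransferase complex, was higher in swi7H4 (0.44, SE 0.0691, adjusted p 0.0251) and dts2 (0.45, adjusted p 0.0118), the only member past the threshold over all genes. None of the genes of the lists that passed over all genes in swi7H4, dts2 or cut4 did so with a common input or with arrays scaled to a common spread. With a common input stc1 differed by 0.0088 in swi7H4 and 0.12 in dts2. When adjusted over the list alone, 1 gene passed in swi7H4, 2 in dts2 (stc1 and epe1) and 0 in cut4. Of 28 DNA replication genes, swi3 was higher in dts2 (0.36, SE 0.0759, adjusted p 0.0361), 1 gene over all genes and 1 adjusted over the list alone, and none passed in the other mutants. The difference of swi3 was -0.05 with a common input. Of 11 genes of the anaphase-promoting complex none passed over all genes in swi7H4 or cut4. When adjusted over the list alone, swi7H4 had 1 higher (apc10) and 1 lower (cut23) and cut4 1 higher (apc2) and 1 lower (apc10). Of 16 heterochromatin-island and meiotic genes none passed over all genes, and adjusted over the list alone only tht2 did, higher with Swi6 than with H3K9me2 (0.28). The island gene mei4 stood at 0.21 in wt, 0.45 in swi7H4, 0.30 in dts2 and 0.47 in cut4 with H3K9me2. With Swi6 it stood at 0.24, 0.51, 0.57 and 0.44. The list median changed with Swi6 by -0.02 in swi7H4, 0.11 in dts2 (12 of 16 above 0, percentile 97.6) and -0.0081 in cut4. With H3K9me2 it changed by -0.0079, 0.06 and -0.05. Of 7 measured subtelomeric genes none passed over all genes and 1 in cut4 adjusted over the list alone (SPBPB8B6.02C). Their median change in cut4 was 0.49 with H3K9me2 and -0.25 with Swi6, and SPAC212.08C differed by -2.07 with Swi6. No gene of the mating-type or Tf2 retrotransposon lists could be measured.

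Ribosomal protein genes, 95 of them, are transcribed strongly and gave a reference for signal at active genes. In dts2 their median change with Swi6 was -0.35 (10 of 95 above 0, below all random draws of genes of like input signal), and it ranged from -0.45 to -0.05 over the scaling alternatives, the latter with a common input. In cut4 the median was 0.15 with both antibodies. In limma 8 were lower in dts2, 10 higher in cut4 and 2 higher in swi7H4 over all genes. Those of dts2 differed, with a common input, by -0.09 to 0.16 and those of cut4 by 0.10 to 0.31, and none passed. Adjusted over the list alone, 2 were higher and 13 lower in dts2, 22 higher and 1 lower in cut4, and 0 in swi7H4. Of 6 core histone genes, hht2 for histone H3 was higher in cut4 (0.71, SE 0.122, adjusted p 0.0284), and differed by 0.18 with a common input. Adjusted over the list alone, 1 was higher in swi7H4 (pht1), 1 in dts2 (cnp1) and 2 in cut4 (hht2 and hta1). The 8 auxotrophic markers, read in the input channel to look for deleted alleles, differed from wt there by -0.12 (arg3) to 0.36 (ura4), at percentiles 22.6 to 97.4 of all genes. These input differences were not tested. At 107 transfer RNA genes outside the centromeres the median Swi6 difference from wt was 0.37 in swi7H4 (221 probes, above all random draws). It was -0.06 in dts2 (percentile 1.14) and 0.07 in cut4. H3K9me2 differed there by 0.01 in swi7H4 and by -0.12 in dts2 and -0.08 in cut4, the last pair below all random draws. At the 17 inside the centromeres Swi6 differed by 0.45 in swi7H4 (22 probes, percentile 99.98), by -0.16 in dts2 and by -0.10 in cut4, and H3K9me2 by -0.05, -0.05 and 0.08. All these transfer RNA medians were read only with each array's own input and without removal of the GC trend. Differences of input or GC content between strains may thus bear on them.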

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

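Apart from the splits of the arrays, normexp and the common spread, the tests of this part, among them the common input, the removal of the GC trend and the division into central and outer probes, were chosen after the data were seen.

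In cut4 the change from wt had opposite signs with the antibodies. At the subtelomeres Swi6 changed by -0.60 and H3K9me2 by 0.61, so the changes lay -1.21 apart. With a common input Swi6 changed there by -0.73 and H3K9me2 by 0.33. At the centromeres Swi6 changed by -0.25 and H3K9me2 by 0.23, -0.48 apart. With 1 array each, these differences were not tested. The tables argue against chromatin of another strain on 1 array: the chromosome III segment found in either cut4 array alone was also higher in the other, by at least 0.56 (spread 0.043). They also argue against a weak Swi6 precipitation as the whole cause, since H3K9me2 over the heterochromatic probes stood at 0.56 in cut4, 0.46 (spread 0.026) above swi7H4, the highest of the other strains.

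An exchange of the antibody labels of cut4 stays open. With the labels exchanged the subtelomere changes were 0.037 and -0.032 and the antibody contrast called 33 bins, all higher with Swi6, among them 18 of 19 in the right and 7 of 7 in the left subtelomere of chromosome I. The Swi6 minus H3K9me2 difference of cut4 outside the regions correlated with those of the other strains at a mean r of 0.10 (spread 0.0041). Exchanged labels were predicted to give a value below 0. That bound was set aside after its value was seen, because antibody and position on the slide go together in every strain. An effect of position would stay with the array if the labels were exchanged. The correlations of cut4 with wt (-0.06), swi7H4 (0.23) and dts2 (0.14) thus cannot decide. The highest was with swi7H4, whose arrays had the same positions as those of cut4. A swap and a true loss of Swi6 with a gain of H3K9me2 in cut4 cannot be told apart, and a biological explanation was not tested otherwise.

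Central centromere probes stood higher in swi7H4 and dts2 than in wt with both antibodies. The tables argue against each of 4 technical causes as the whole cause. With a common input the lowest of the 4 changes was 0.53 (spread 0.079), and each exceeded the upper 95% limit of stretches of like GC content by at least 0.30 (spread 0.071, 43 such stretches at centromere 2), although GC content goes with part of the Swi6 change, since those stretches rose by a mean of 0.35 in swi7H4 and 0.32 in dts2 and removal of the trend took it from 0.87 to 0.44 and from 0.75 to 0.41. In swi7H4, on the slide of wt, the lower change was 0.73 (spread 0.12). With channel backgrounds set to make the change least, the lowest of the 4 was 0.65 (spread 0.12). The backgrounds ranged between none and the 95th percentile of the negative controls. The central rise also went with a wider grouping of the arrays, which was not tested. Median input signals were 5400 to 5953 in wt and cut4 and 7887 to 8313 in swi7H4 and dts2. Central levels in cut4 were -0.07 and -0.20, near those of wt (-0.24 and -0.10). With a common input, however, the central change of cut4 was -0.02 with H3K9me2 (percentile 21.9) and -0.25 with Swi6 (percentile 0.04). With Swi6 cut4 thus lay below wt there. A difference in chromatin preparation between these pairs of strains thus stays open. More H3K9me2 and Swi6 in the central domain of both mutants is a hypothesis, found and tested on the same data and wt arrays. The change of cut4, 0.17 and -0.10 there, argues against low values in wt alone and, for dts2, against the slide as the whole cause. In swi7H4 the H3K9me2 level was 0.48 there, but 0.17 at the outer probes, -0.03 in the mating-type region and 0.04 at the subtelomeres. In dts2 these levels were 0.57, 0.16, -0.04 and -0.02. The mitochondrial genome, which carries no histones, also rose with H3K9me2, from -2.23 in wt to -0.66 in swi7H4, partly through its input. Whether the central signal reflects the mark itself thus stays open.

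Of the alternative probe values, only normexp, chosen beforehand, removed the central difference. The others put it at 0.41 to 1.39, the lowest with the GC trend removed (Swi6 in dts2), and normexp put it at 0.028 and 0.16 in swi7H4 and 0.081 and 0.15 in dts2. It fitted a mean background of 3213 to 14829 intensity units over all channels, whereas the negative controls had medians of 71.7 to 106.5, so it subtracted signal rather than background.

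The many bins that differed from wt in swi7H4 or dts2 followed the input channel. Summed over both contrasts there were 2516 calls, and a bin called in both mutants counts in each. With a common input 1 call was left, in swi7H4, and 0 bins passed both ways in either contrast. The median difference over the called bins went from 0.34 to 0.03 in swi7H4 and from 0.33 to -0.00087 in dts2, while the median SE went only from 0.0774 to 0.0695 and from 0.0770 to 0.0692, so the calls ended because the differences did. With arrays scaled to a common spread 0 bins passed too, at smaller median differences (0.21 and 0.22) and slightly larger median SEs (0.0826 and 0.0810). GC content alone is argued against, since both contrasts together held 2914 calls with its trend removed and 2233 of the same kind before. The wt input minus that of both mutants was 0.27 (SE 0.0080) higher at probes between genes than inside them, and 0.19 in the same measure for cut4, which suggests that input chromatin of wt and cut4 held more DNA from between genes.

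Both remaining signals were noted because the input channel, not compared by itself in the report, differed from wt, but the immunoprecipitate differed too. On chromosome III the cut4 segment (1578000 to 1599999) stood 0.44 above wt in the input as a mean of both arrays, and 0.65 in the immunoprecipitate of each. At the mating-type locus the input of the bin that holds mat1 (chromosome II 2114000 to 2115999) stood 1.46 above wt in swi7H4 (1.76 and 1.15 on its arrays). This value rests on 1 of the 3 probes, which differed by 6.28 and 4.58 (in the immunoprecipitate from -6.67 to -1.71 and from -5.21 to -1.89 against the array median), while the others averaged -0.50 and -0.56 in the input. No explanation was tested for either signal.

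For the antibody contrast the other splits of the arrays say nothing about chance: the real split called 0 bins and 0 genes, so each of the 32 that could be fitted had to give as many (32 of 32 for bins and 32 of 32 for genes). The highest of the others called 381 bins and 397 genes. It was reached by 2 splits, which keep wt and cut4 whole and part swi7H4 and dts2 by antibody. With strain as block these 2 splits are the same contrast with the sign reversed. They compare Swi6 with H3K9me2 in swi7H4 and dts2 alone. Of the 8 splits that part both arrays of every strain, 1 had any call, 33 bins and 1 gene (SPAC212.08C), and it is the one with the cut4 labels exchanged.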

How the results depend on the processing

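The common input, the removal of the GC trend, the omission of saturated probes, the exchange of the cut4 labels, the split into central and outer probes (also with the GC trend removed), the fits within slides and the 60-kb window were chosen after the data were seen, and the others before. Signal lay far above background on all arrays, so depth limits little. A main limit is 1 array per strain and antibody. Another is that the wt H3K9me2 array had no enriched bin and hardly set the heterochromatic regions apart. This bears on each H3K9me2 change from wt. Of 270 alternative values for the 18 changes of regions from wt, 250 kept their sign, and of the 186 among them that were planned 179 did. The series matrix, centring outside the regions, the filter on background and keeping outlier spots moved no level of a region beyond its spread. The antibody contrast stayed at 0 bins and 0 genes with no block (112 bins and 115 genes at an unadjusted p under 0.05 in limma) and with the slide as block (102 and 117). Leaving out each strain gave 0 to 27 bins, 27 without cut4 (684 at an unadjusted p under 0.05) and 0 without wt (770), swi7H4 (192) or dts2 (158). The values that moved beyond their spread, changed sign or moved a count by more than 1.5 times were as follows. Except for normexp, which took signal for background, and for changes of the bins, probes or threshold, which act by construction, the cause was not tested.

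With normexp background correction, the count of enriched bins was 1 in wt H3K9me2, 4 in swi7H4 H3K9me2, 1 in dts2 H3K9me2 and 18 in cut4 Swi6. The strain contrast called 745 bins in cut4, 328 genes in swi7H4, 380 genes in dts2 and 237 genes in cut4. The pericentromere change was -0.019 in swi7H4 H3K9me2 (opposite sign), 0.15 in swi7H4 Swi6, -0.0028 in dts2 H3K9me2 (opposite sign), -0.030 in dts2 Swi6 (opposite sign) and 0.11 in cut4 H3K9me2. The pericentromere level was 0.17 in wt H3K9me2 (opposite sign), 0.40 in wt Swi6, 0.15 in swi7H4 H3K9me2, 0.56 in swi7H4 Swi6, 0.17 in dts2 H3K9me2, 0.38 in dts2 Swi6 and 0.13 in cut4 Swi6. The mating-type change was 0.24 in swi7H4 H3K9me2 and -0.074 in cut4 Swi6. The mating-type level was 0.049 in swi7H4 H3K9me2 (opposite sign), 0.14 in swi7H4 Swi6 and 0.023 in dts2 Swi6. The subtelomere change was 0.17 in swi7H4 Swi6 and -0.24 in dts2 Swi6. The subtelomere level was 0.031 in wt H3K9me2 (opposite sign), 0.74 in wt Swi6, 0.14 in swi7H4 H3K9me2, 0.91 in swi7H4 Swi6, 0.080 in dts2 H3K9me2 (opposite sign), 0.62 in cut4 H3K9me2 and 0.12 in cut4 Swi6 (opposite sign). With loess within arrays, the count of enriched bins was 1 in wt H3K9me2 and 0 in swi7H4 H3K9me2. It called 1887 bins in swi7H4, 2102 bins in dts2, 893 bins in cut4, 535 genes in swi7H4, 671 genes in dts2 and 529 genes in cut4 in the strain contrast. Values of 0.40 in swi7H4 Swi6, 0.14 in dts2 Swi6 and -0.19 in cut4 Swi6 were found for the pericentromere change. Values of 0.14 in wt H3K9me2 (opposite sign), 0.45 in wt Swi6, 0.51 in swi7H4 H3K9me2, 0.50 in dts2 H3K9me2, 0.60 in dts2 Swi6, 0.39 in cut4 H3K9me2 and 0.26 in cut4 Swi6 were found for the pericentromere level. Values of 0.18 in swi7H4 Swi6, -0.15 in dts2 Swi6 and -0.51 in cut4 Swi6 were found for the subtelomere change. Values of 0.065 in wt H3K9me2 (opposite sign), 0.68 in wt Swi6, 0.16 in swi7H4 H3K9me2, 0.083 in dts2 H3K9me2 (opposite sign), 0.53 in dts2 Swi6, 0.64 in cut4 H3K9me2 and 0.17 in cut4 Swi6 (opposite sign) were found for the subtelomere level. With arrays scaled to a common spread, the count of enriched bins was 11 in wt Swi6, 2 in swi7H4 H3K9me2, 25 in dts2 Swi6 and 8 in cut4 H3K9me2. The strain contrast called 0 bins in swi7H4, 0 bins in dts2, 0 bins in cut4, 0 genes in swi7H4, 0 genes in dts2 and 0 genes in cut4, while 903, 1032 and 674 bins and 496, 556 and 507 genes had an unadjusted p under 0.05 in limma. The pericentromere change was 1.25 in swi7H4 Swi6, 0.58 in dts2 Swi6 and -0.19 in cut4 Swi6. The pericentromere level was 1.46 in swi7H4 Swi6 and 0.78 in dts2 Swi6. A value of 0.32 in swi7H4 Swi6 was found for the mating-type change. A value of 0.38 in swi7H4 Swi6 was found for the mating-type level. The subtelomere change was 1.04 in swi7H4 Swi6, 0.27 in dts2 Swi6 (opposite sign), 0.53 in cut4 H3K9me2 and -0.46 in cut4 Swi6. The subtelomere level was 0.43 in wt Swi6, 1.47 in swi7H4 Swi6, 0.70 in dts2 Swi6 and 0.47 in cut4 H3K9me2. With the median over probes, the count of enriched bins was 2 in swi7H4 H3K9me2 and 6 in cut4 Swi6. It called 573 bins in swi7H4, 665 bins in dts2, 172 bins in cut4 and 232 genes in cut4 in the strain contrast. A value of -0.14 in cut4 Swi6 was found for the pericentromere change. Values of 0.059 in wt Swi6, 0.79 in swi7H4 Swi6 and 0.14 in cut4 H3K9me2 were found for the pericentromere level. The mating-type change was -0.022 in cut4 Swi6. The mating-type level was -0.031 in wt H3K9me2, 0.067 in swi7H4 H3K9me2 (opposite sign), 0.16 in swi7H4 Swi6 and 0.041 in cut4 Swi6 (opposite sign). Values of 1.07 in swi7H4 Swi6 and 0.62 in cut4 H3K9me2 were found for the subtelomere level.

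With multi-match probes left out, the subtelomere change was 0.35 in swi7H4 Swi6, 0.017 in dts2 Swi6 (opposite sign), 0.54 in cut4 H3K9me2 and -0.54 in cut4 Swi6. The subtelomere level was 0.44 in wt Swi6, -0.010 in swi7H4 H3K9me2 (opposite sign), 0.79 in swi7H4 Swi6, -0.069 in dts2 H3K9me2, 0.46 in dts2 Swi6, 0.44 in cut4 H3K9me2 and -0.10 in cut4 Swi6. With 1-kb bins, the count of enriched bins was 1 in wt H3K9me2, 3 in swi7H4 H3K9me2, 17 in dts2 Swi6, 24 in cut4 H3K9me2 and 22 in cut4 Swi6. The strain contrast called 2147 bins in swi7H4, 2396 bins in dts2 and 645 bins in cut4. With 5-kb bins, the count of enriched bins was 8 in wt Swi6, 0 in swi7H4 H3K9me2, 11 in swi7H4 Swi6, 5 in dts2 Swi6, 6 in cut4 H3K9me2 and 0 in cut4 Swi6. It called 451 bins in swi7H4, 495 bins in dts2 and 98 bins in cut4 in the strain contrast. With an enrichment threshold of 0.58, the count of enriched bins was 13 in wt H3K9me2, 58 in wt Swi6, 9 in swi7H4 H3K9me2, 5 in dts2 H3K9me2, 29 in dts2 Swi6, 60 in cut4 H3K9me2 and 80 in cut4 Swi6. With an enrichment threshold of 1.5, the count of enriched bins was 7 in wt Swi6, 0 in swi7H4 H3K9me2, 15 in swi7H4 Swi6, 0 in dts2 Swi6, 0 in cut4 H3K9me2 and 0 in cut4 Swi6. With subtelomeres of 20 kb, the subtelomere change was 0.30 in swi7H4 H3K9me2, 0.063 in swi7H4 Swi6, 0.14 in dts2 H3K9me2, -0.58 in dts2 Swi6, 1.13 in cut4 H3K9me2 and -1.23 in cut4 Swi6. The subtelomere level was 0.063 in wt H3K9me2 (opposite sign), 1.46 in wt Swi6, 0.37 in swi7H4 H3K9me2, 1.52 in swi7H4 Swi6, 0.21 in dts2 H3K9me2 (opposite sign), 0.88 in dts2 Swi6, 1.19 in cut4 H3K9me2 and 0.23 in cut4 Swi6 (opposite sign). With subtelomeres of 100 kb, the subtelomere change was 0.24 in swi7H4 Swi6, 0.11 in dts2 H3K9me2, 0.11 in dts2 Swi6 (opposite sign), 0.26 in cut4 H3K9me2 and -0.18 in cut4 Swi6. Values of -0.21 in wt H3K9me2, 0.0020 in wt Swi6, -0.13 in swi7H4 H3K9me2 (opposite sign), 0.24 in swi7H4 Swi6, -0.10 in dts2 H3K9me2, 0.12 in dts2 Swi6, 0.046 in cut4 H3K9me2 and -0.18 in cut4 Swi6 were found for the subtelomere level. With pericentromeres extended by 5 kb, the pericentromere change was 0.17 in swi7H4 H3K9me2, 0.25 in swi7H4 Swi6, 0.20 in dts2 H3K9me2, 0.066 in dts2 Swi6 and -0.17 in cut4 Swi6. The pericentromere level was 0.15 in swi7H4 H3K9me2, 0.45 in swi7H4 Swi6, 0.18 in dts2 H3K9me2 and 0.27 in dts2 Swi6. With pericentromeres trimmed by 5 kb, the pericentromere change was 0.62 in swi7H4 H3K9me2, 0.74 in swi7H4 Swi6, 0.67 in dts2 H3K9me2 and 0.57 in dts2 Swi6. Values of -0.14 in wt H3K9me2, 0.15 in wt Swi6, 0.48 in swi7H4 H3K9me2, 0.53 in dts2 H3K9me2, 0.72 in dts2 Swi6, 0.12 in cut4 H3K9me2 and -0.10 in cut4 Swi6 (opposite sign) were found for the pericentromere level. With trend and robust eBayes, the strain contrast called 647 bins in cut4 and 318 genes in cut4.

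With saturated probes left out, the subtelomere change was 0.37 in swi7H4 Swi6, 0.032 in dts2 Swi6 (opposite sign), 0.54 in cut4 H3K9me2 and -0.52 in cut4 Swi6. Values of 0.41 in wt Swi6, -0.020 in swi7H4 H3K9me2 (opposite sign), 0.78 in swi7H4 Swi6, -0.073 in dts2 H3K9me2, 0.45 in dts2 Swi6, 0.43 in cut4 H3K9me2 and -0.10 in cut4 Swi6 were found for the subtelomere level. With the common input, the count of enriched bins was 3 in swi7H4 H3K9me2 and 1 in cut4 Swi6. The strain contrast called 1 bin in swi7H4, 0 bins in dts2, 10 bins in cut4, 0 genes in swi7H4, 0 genes in dts2 and 5 genes in cut4. The pericentromere change was 0.20 in swi7H4 H3K9me2, 0.21 in dts2 H3K9me2 and 0.13 in cut4 H3K9me2. The pericentromere level was 0.80 in swi7H4 Swi6 and 0.49 in dts2 Swi6. Values of 0.021 in swi7H4 H3K9me2, 0.047 in swi7H4 Swi6, -0.038 in dts2 H3K9me2 (opposite sign) and -0.12 in dts2 Swi6 (opposite sign) were found for the mating-type change. Values of -0.10 in swi7H4 H3K9me2, -0.16 in dts2 H3K9me2 and 0.015 in dts2 Swi6 were found for the mating-type level. Values of -0.15 in swi7H4 H3K9me2 (opposite sign), 0.089 in swi7H4 Swi6, -0.19 in dts2 H3K9me2 (opposite sign), -0.18 in dts2 Swi6, 0.33 in cut4 H3K9me2 and -0.73 in cut4 Swi6 were found for the subtelomere change. The subtelomere level was 0.15 in wt H3K9me2 (opposite sign), 0.64 in wt Swi6, 0.0023 in swi7H4 H3K9me2, 0.72 in swi7H4 Swi6, 0.45 in dts2 Swi6, 0.48 in cut4 H3K9me2 and -0.10 in cut4 Swi6. With the GC trend removed, the count of enriched bins was 10 in wt Swi6, 0 in swi7H4 H3K9me2, 11 in swi7H4 Swi6, 2 in dts2 Swi6, 9 in cut4 H3K9me2 and 0 in cut4 Swi6. It called 935 bins in cut4, 582 genes in swi7H4, 643 genes in dts2 and 649 genes in cut4 in the strain contrast. Values of 0.24 in swi7H4 Swi6 and -0.00087 in dts2 Swi6 (opposite sign) were found for the pericentromere change. Values of 0.27 in wt H3K9me2 (opposite sign), 0.60 in wt Swi6, 0.59 in swi7H4 H3K9me2, 0.57 in dts2 H3K9me2, 0.61 in dts2 Swi6, 0.53 in cut4 H3K9me2 and 0.36 in cut4 Swi6 were found for the pericentromere level. The mating-type change was 0.039 in swi7H4 Swi6. The mating-type level was 0.051 in swi7H4 H3K9me2 (opposite sign) and 0.013 in cut4 Swi6 (opposite sign). With a 60-kb window around centromere 1, the pericentromere change was 0.34 in swi7H4 Swi6, 0.26 in dts2 H3K9me2, 0.15 in dts2 Swi6 and -0.14 in cut4 Swi6. The pericentromere level was 0.093 in wt Swi6, 0.15 in swi7H4 H3K9me2, 0.44 in swi7H4 Swi6, 0.14 in dts2 H3K9me2, 0.25 in dts2 Swi6 and 0.11 in cut4 H3K9me2. With the cut4 antibody labels exchanged, the antibody contrast called 33 bins and 1 gene. The pericentromere change was 0.014 in cut4 H3K9me2 and -0.040 in cut4 Swi6. Values of 0.078 in cut4 H3K9me2 and -0.030 in cut4 Swi6 were found for the mating-type change. The subtelomere change was 0.037 in cut4 H3K9me2 and -0.032 in cut4 Swi6. With central probes alone, the pericentromere change was 0.73 in swi7H4 H3K9me2, 0.87 in swi7H4 Swi6, 0.81 in dts2 H3K9me2, 0.75 in dts2 Swi6 and -0.10 in cut4 Swi6. With outer probes alone, the pericentromere change was -0.018 in swi7H4 H3K9me2 (opposite sign), 0.36 in swi7H4 Swi6, -0.028 in dts2 H3K9me2 (opposite sign), -0.11 in dts2 Swi6 (opposite sign) and -0.38 in cut4 Swi6. With central probes alone and the GC trend removed, the pericentromere change was 0.72 in swi7H4 H3K9me2, 0.44 in swi7H4 Swi6, 0.74 in dts2 H3K9me2, 0.41 in dts2 Swi6 and -0.089 in cut4 Swi6. With outer probes alone and the GC trend removed, the pericentromere change was -0.016 in swi7H4 H3K9me2 (opposite sign), 0.060 in swi7H4 Swi6, -0.076 in dts2 H3K9me2 (opposite sign), -0.36 in dts2 Swi6 (opposite sign), 0.31 in cut4 H3K9me2 and -0.38 in cut4 Swi6. Removal of the GC trend gave no value for the subtelomeres, where the probes of the right end of chromosome I have no matched sequence.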

Other observations

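These values were chosen after the data were seen, and no explanation was tested. The mitochondrial genome, which carries no histones, had log2 ratios of -2.23 with H3K9me2 and -1.81 with Swi6 in wt, -0.66 and -0.70 in swi7H4, -0.65 and -0.29 in dts2, and -1.81 and -1.92 in cut4. Its input signal against wt was -1.01 and -1.21 in swi7H4, -1.10 and -1.37 in dts2, and 0.07 and 0.06 in cut4, and 53 of its 66 probes were saturated on some array. A probe at mat1 (chromosome II 2115566 to 2115625) had an input signal against the array median of -8.32 and -6.60 in wt, -2.03 and -2.02 in swi7H4, -3.69 and -3.71 in dts2, and -5.95 and -5.72 in cut4. On the wt arrays it was close to background (raw input signals of 92.2 and 130 against negative-control medians of 71.7 and 72.1), so its log values there are imprecise. Input signals outside the regions correlated across probes, which are not independent replicates, at 0.977 to 0.981 between swi7H4 and dts2, on different slides, and at 0.897 to 0.912 between wt and swi7H4, on the same slide. The log ratio correlated with GC content across probes at 0.30 with H3K9me2 and 0.42 with Swi6 in wt, 0.52 and -0.02 in swi7H4, 0.47 and 0.05 in dts2, and 0.51 and 0.51 in cut4.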
